A study of Bradyrhizobium japonicum with 6 samples.

How the data were processed

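Total RNA was extracted with hot phenol and copied to cDNA with random hexamers, and the cDNA was labelled with Cy3 or Cy5, per the labels' protocols. Per the file headers, the deposited spot intensity values are mean pixel intensities with a local background mean and SD in each channel, from image analysis software of the ImaGene type. They are neither background-subtracted nor normalised. Each spot also carries a quality mark and the tests behind it, which are other values the authors deposited as the software gave them. The authors also deposited a processed ratio per probe and array. Its scale, centring and direction were unstated and were settled against the scanner values: the log2 of the deposited ratio correlated with the log2 of Cy5 over Cy3 at r of 0.932 to 0.961 with slopes of 0.956 to 1.07, and the medians of the ratio were 0.991 to 1.023. It is a linear ratio of Cy5 over Cy3. On wild-type array 3 it was listed at 0 for 130 probes and missing for 49, and these were left out. The authors' normalization is not given in the sources used here.

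Each array has 18240 spots in 48 printing blocks. Of these, 16960 are gene spots, 2 for each of 8480 probes, and 1280 are control or empty spots. Spots marked by hand or as poor were left out (3.40% of gene spots), except those marked only for saturation. The exact form of this rule was set after the files were seen. Values left out were most frequent among the 848 brightest probes, at 5.33% of values against at most 0.69% in any dimmer set of 848 probes, so bright genes such as mntH lost arrays. Background was corrected with normexp and an offset of 50, each array was normalised with global loess with control and left-out spots at weight 0, and the 2 spots of a probe were averaged. Spots of a probe correlated at 0.737 to 0.877 within arrays. Different probes of a gene were tested separately.

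One group-means model over the 6 arrays was fitted with limma 3.58.1 in R 4.3.3, with eBayes and Benjamini-Hochberg adjustment at a threshold of 0.05. The indirect comparison is the sum of the group means. A probe not above background on any array of a group in the channel concerned has a fold given as a lower bound, from per-channel levels after loess and Aquantile, which is open to dye bias because dyes were not swapped. Where the dim signals themselves lay above the lowest signal of probes above background, that bound equals the fitted fold, as for bll5572, dnaC and blr7813. Log2 values and ranges printed for such probes are fitted values. A bound on the indirect sum adds the values of both groups of arrays, with the bound in place of each ratio that has one. Separate-channel fits used the same levels, with statmod 1.5.0. Gene lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation, over probes measured on all arrays and for lists of at least 5 members; lists on separate-channel values were tested with the preset only. On simulated data for 8263 probes with 200 changed, the model recovered 32.8% of changes of 0.5 on the log2 scale and 95.2% of changes of 1 in the wild-type comparison, with 4.18% of calls false. For the indirect comparison it recovered 7.5% and 71%. In 40 simulations the shifted list was found 40 times, and 1 of 760 unshifted lists was called. The simulated probes varied independently of each other. These runs therefore do not show how the preset correlation performs on lists whose members vary together.

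The comparisons, the tests, the rule for named genes and most other settings tried were fixed before the data were examined. Named genes are the 10 highest and 10 lowest mean log2 ratios among probes past the threshold and measured with the same sign on all 3 arrays. Probes with a value on fewer arrays are therefore not ranked. For the indirect comparison the same sign was asked of the sums of same-numbered arrays, although whether the numbers pair the arrays is not settled. Also named are mnoP, mntH, mur and irr, and the 4 members with the smallest adjusted p of each list that passed. Gene names come from a platform annotation that lists a symbol for 8462 probes, mostly the locus tag, and no product. The planned lists could not be matched by product. Instead, 26 lists were written as gene symbol patterns after that table was seen and before ratios were computed, and 23 of them were tested. They include lists that were not planned, among them Flp pilus, uptake hydrogenase, carbon dioxide fixation, purine and pyrimidine biosynthesis and fatty acid synthesis. The planned lists of amino acid transport, sugar transport and transposases were not kept. Alternatives covered background, normalization, quality marks, dim probes (brighter than background plus 2 SD in a channel on at least 3 arrays), duplicate spots, samples in the fit, replicate and slide series blocks, leaving out each array, moderation, a 2-fold threshold and the deposited ratios. Slide series in the titles and day of quantification split the arrays the same way: 2 wild-type arrays against the other wild-type array and the mur arrays. The names of the deposited files carry the same series for all 6 arrays, so series rests on the titles, while the split by day stands on its own. Genome coordinates were not used here.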

Results

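Gene expression was measured in the soybean symbiont Bradyrhizobium japonicum USDA110 on 6 two-colour arrays, in 2 groups of 3 arrays. On the 3 wild-type arrays, Cy5 carried cDNA of wild-type cells grown without manganese and Cy3 that of wild-type cells grown with manganese. On the 3 mur arrays, Cy5 carried cDNA of a mur mutant grown with manganese, and Cy3 is labelled as wild-type cells grown without manganese. Mur is a Fur-family regulator that responds to manganese. The labels call the cultures independent biological materials. Dyes were not swapped, so a dye effect on a probe is part of each ratio. The median spot signal was 3.25 to 4.87 times the local background in Cy5 and 2.81 to 5.20 times in Cy3, and the number of arrays limits the precision. Each array held 8480 gene probes as 2 spots each.

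The first comparison asked which wild-type transcripts changed when manganese was withheld. Transcripts of manganese uptake were much higher in Mn-deplete cells. The probe of mnoP (blr0095), an outer membrane manganese channel, was at least 31.6-fold higher, with a log2 ratio of 5.11 ± 0.92 (SD, n = 3; limma adjusted p = 0.00015). The probe of mntH (bll5044), the manganese transporter of the inner membrane, kept 1 array after spots marked as poor were left out, with a log2 ratio of 4.74. With every spot kept, the mntH log2 ratio was 4.92 ± 0.17 (SD, n = 3; limma adjusted p = 9.77e-07). The iron response regulator irr (bll0768) was 4.23-fold higher, with a log2 ratio of 2.08 ± 0.13 (SD, n = 3). The probe listed as fur (bll0797), which is mur, had a log2 ratio of 0.42 ± 0.18 (SD, n = 3; limma adjusted p = 0.0327), and this call was lost without any 1 of the wild-type arrays, with slide series as a block (0.301), within the first (0.439) or second series (0.0597), with a normexp offset of 0 (0.0512) and with trend and robust moderation (0.0506).

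Other strong increases in Mn-deplete cells were at loci whose products are not given in the sources used here. The probe of blr1115 was at least 10.8-fold higher and that of bll5572 at least 8.97-fold higher with every spot kept and 10.1-fold with marked spots left out. The log2 ratio was 3.34 ± 0.28 for bll2512, 3.23 ± 0.77 for blr6532, 3.11 ± 0.59 for blr2520 and 2.82 ± 0.82 for blr6531 (SD, n = 3). The probe listed as dnaC (bll4072) was at least 7.81-fold higher, and blr7813 at least 5.53-fold higher. The small heat shock gene hspH (bll0729) was 5.74-fold higher. Among the lowest ratios, fla (bll6865), a flagellin gene, had a log2 ratio of -2.77 ± 0.96, and its neighbour bll6866 one of -2.31 ± 0.66 (SD, n = 3). The flagellar rod gene flgC (bll5813) was at least 3.49-fold lower in Mn-deplete cells. The probes of bll7406, bsr1505, bll5844 and bll5085 had log2 ratios of -2.34, -2.23, -2.19 and -2.16. The probes of bll7927 and bll7405 were at least 2.84-fold and 3.18-fold lower, and blr2347 had a log2 ratio of -1.82 ± 0.23 (SD, n = 3).

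**Figure D1:**
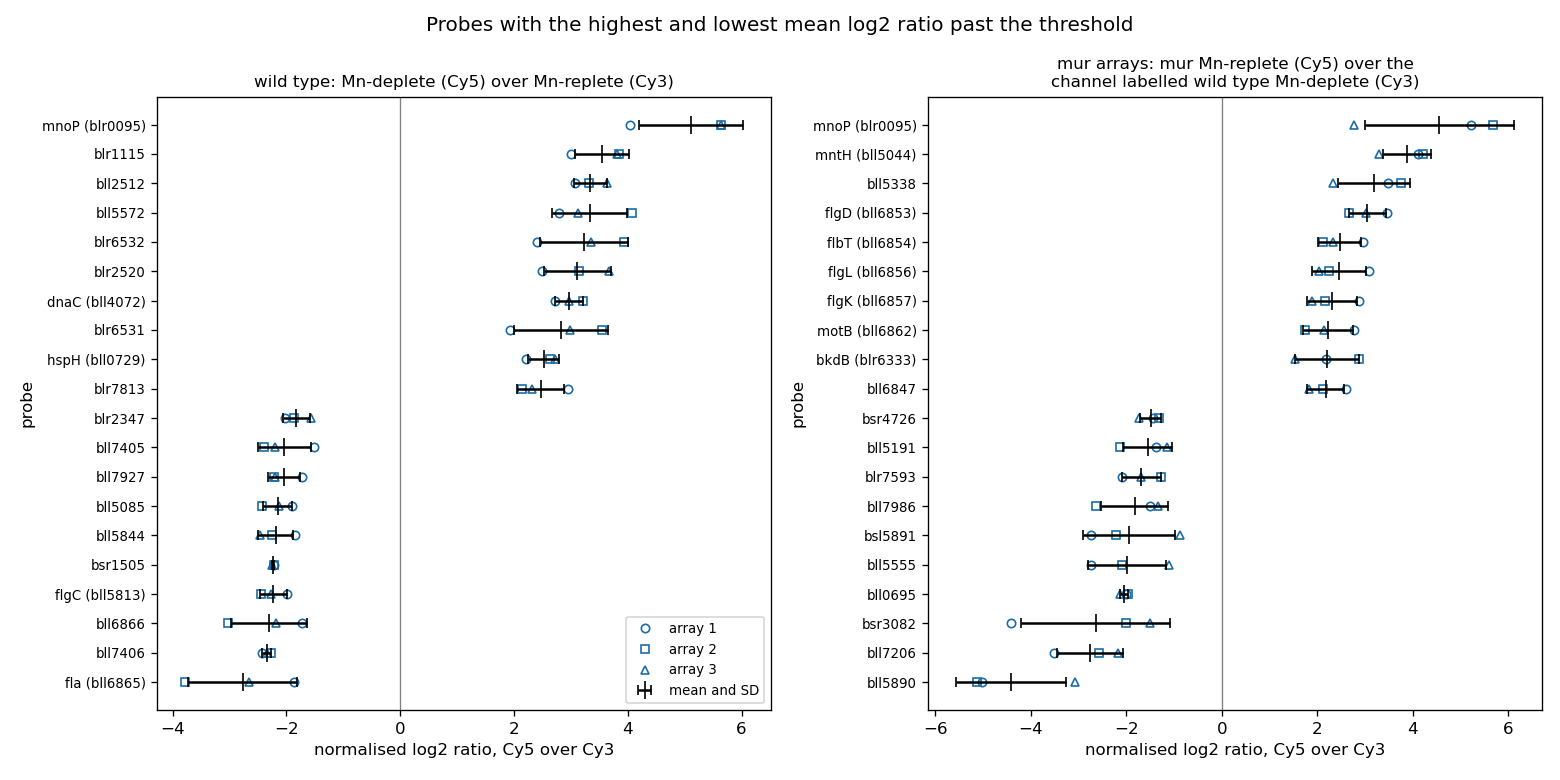
Normalised log2 ratio (horizontal axis) of the 10 highest and 10 lowest probes among those past the threshold and measured with the same sign on all 3 arrays (vertical axis), for the wild-type arrays (left) and the mur arrays (right). Open symbols are single arrays, and the bar with whiskers is the mean with its SD. The mnoP probe leads both panels, with means of 5.11 and 4.56.

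Genes of motility and chemotaxis were lower as a group in Mn-deplete cells. Of 70 measured members, 32 fell, 0 rose and 38 did not pass the test, with a median log2 ratio of -0.49. Examples are cheY (blr2194) at -1.22 and cheA (blr2343) at -1.08, both of chemotaxis signalling, while fliG (blr7000), of the flagellar switch, was at least 2.21-fold lower. The camera test with a preset correlation gave an adjusted p of 9.8e-13, against an adjusted p = 0.416 with an estimated correlation. Of 17 measured genes of Flp pilus assembly, 13 fell, 2 rose and 2 did not pass. The log2 ratio of ctpC (bll1440) was -1.73, that of ctpD (bll1439) -1.72 and that of ctpA (bsl7141) -1.21, and ctpE (bll1438) was at least 2.81-fold lower. The camera adjusted p of this list was 2.86e-05 with the preset and adjusted p = 0.416 with an estimated correlation. With slide series as a block, the median log2 ratio was -0.30 for motility and -0.79 for Flp pilus, and within the first series -0.35 and -0.82, both resting on 1 wild-type array. Of 42 measured genes of chaperones and heat shock, 16 rose and 2 fell, but the list did not pass (camera adjusted p = 0.0753). Of 10 measured genes of heme and iron uptake, 0 rose and 2 fell (camera adjusted p = 0.735).

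Over all 8458 probes tested, limma with Benjamini-Hochberg adjustment called 2394, of which 1308 were higher and 1086 lower in Mn-deplete cells. At a change of at least 2-fold, 228 were higher and 140 lower. With median centring in place of loess, 1677 were higher and 750 lower. The count was 900 without wild-type array 2 and 939 without wild-type array 3. With slide series as a block it was 228, within the first series, which holds 1 of the 3 wild-type arrays, 59, and within the second series 3052. In the block and first-series fits the wild-type mean rests on that 1 array, which is assumed to vary like the other arrays in the fit. Within the first series the calls of mnoP (blr0095), bll6866, bsr1505, bll5085, cheY (blr2194), cheA (blr2343), fliG (blr7000) and ctpA (bsl7141) were lost, with the same sign.

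The second comparison set the mur mutant grown with manganese against the channel labelled wild type Mn-deplete. Transcripts of manganese uptake were higher in the mutant channel on these arrays. The mnoP probe (blr0095) had a log2 ratio of 4.56 ± 1.57 and the mntH probe (bll5044) one of 3.88 ± 0.51 (SD, n = 3; limma adjusted p = 0.000528 and 0.000118). The irr probe (bll0768) was 3.32-fold higher, with a log2 ratio of 1.73 ± 0.34 (SD, n = 3). The probe of mur itself, listed as fur (bll0797), had a log2 ratio of 0.88 ± 0.25 (SD, n = 3; limma adjusted p = 0.00185). Its position relative to the disruption is not given in the sources used here, so its signal checks nothing about the strain.

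In the channel labelled wild type Mn-deplete, the levels of mnoP, mntH and blr1115 lay far below those of the Mn-deplete channel of the wild-type arrays. On a log2 scale with every spot kept, mnoP (blr0095) had a level of 7.57 ± 0.96 there, 7.45 ± 0.32 in the Mn-replete channel and 12.70 ± 0.50 in the Mn-deplete channel of the wild-type arrays (SD, n = 3). For mntH (bll5044) the levels were 8.28 ± 0.68, 8.44 ± 0.25 and 13.36 ± 0.41, and for blr1115 they were 7.85 ± 0.02, 7.36 ± 0.25 and 10.92 ± 0.24 (SD, n = 3). For mur (bll0797) they differed less, at 8.38 ± 0.46, 8.73 ± 0.085 and 9.15 ± 0.14 (SD, n = 3). The Cy3 signal of mnoP was not above background on 3 of 3 wild-type and 2 of 3 mur arrays, that of blr1115 on 3 of 3 wild-type arrays and that of mntH on 1 of 3 mur arrays. The low levels of mnoP and blr1115 are therefore partly background and do not show that the channels were equal. In a separate-channel limma fit of 8263 probes, this channel differed from the Mn-replete channel at 0 probes, with 227 at an unadjusted p under 0.05. It differed from the Mn-deplete channel of the wild-type arrays at 300 probes, with 1744 at an unadjusted p under 0.05. The first contrast is Cy3 against Cy3 and the second Cy3 against Cy5, so a dye effect on a probe enters only the second. Every direction on the mur arrays below is therefore stated against the channel labelled wild type Mn-deplete, whose values go against its label.

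**Figure D2:**
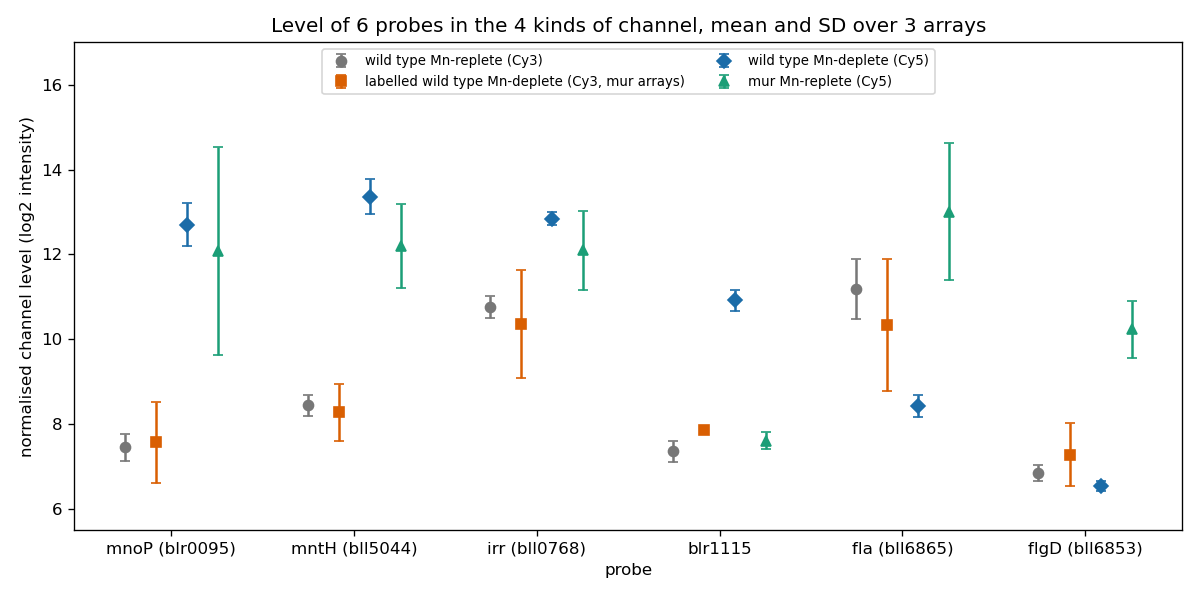
Normalised log2 intensity (vertical axis) of 6 probes (horizontal axis) in the 4 kinds of channel, as means with SD over 3 arrays. For mnoP the channel labelled wild type Mn-deplete lies at 7.57 and the Mn-replete channel at 7.45, both partly background, below the Mn-deplete channel at 12.70.

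Motility genes were higher as a group in the mutant channel. Of 70 measured members, 40 rose, 1 fell and 29 did not pass, with a median log2 ratio of 0.53. The hook gene flgD (bll6853) was at least 7.71-fold higher. The log2 ratio was 2.47 for the flagellin regulator flbT (bll6854), 2.46 for flgL (bll6856), 2.31 for flgK (bll6857), 2.22 for the motor gene motB (bll6862) and 2.10 for fliC (bll6855). The probes of fla (bll6865) and bll6866 were among the lowest on the wild-type arrays. With every spot kept, they had 2.67 ± 0.62 and 2.73 ± 0.43 on the mur arrays (SD, n = 3). The camera adjusted p was 8.89e-13 with the preset and adjusted p = 0.243 with an estimated correlation. Of 53 measured genes of ribosomal proteins, 48 rose and 0 fell, with a median log2 ratio of 0.80. Examples are rplY (bll7441) at 1.17, rpsE (bll5383) at 1.19, rpmC (bsl5392) at 1.12 and rplS (blr0487) at 1.05. Their camera adjusted p was 9.09e-24 with the preset and adjusted p = 0.243 with an estimated correlation.

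Genes of energy metabolism and biosynthesis also passed as lists on the mur arrays. Of 59 measured genes of respiration and ATP synthase, 24 rose and 2 fell (camera adjusted p = 0.000522, and adjusted p = 0.243 with an estimated correlation). The oxidase gene cyoC (blr0151) had a log2 ratio of 1.82, cyoD (blr0152) 1.31, atpA (bll0442) 1.47 and atpB (bll1185) 1.39. Of 20 genes of purine and pyrimidine biosynthesis, 8 rose and 1 fell (camera adjusted p = 0.00117, and adjusted p = 0.243 with an estimated correlation), with purF (bll4060) at 1.04 and pyrG (bll4805) at 1.10. Of 24 genes of fatty acid synthesis, 8 rose and 0 fell (camera adjusted p = 0.0302, and adjusted p = 0.243 with an estimated correlation), with accB (bll4291) at 1.10 and fabF (blr4085) at 0.76. Of 19 genes of the TCA cycle and pyruvate, 8 rose and 1 fell (camera adjusted p = 0.0468, and adjusted p = 0.243 with an estimated correlation), with mdh (bll0456) at 1.42 and pdhA (bll4783) at 1.13. The estimated correlation was -0.027 for fatty acid synthesis and -0.049 for the TCA cycle, below the preset of 0.01. Their higher adjusted p with it therefore does not show that their members vary together. The TCA call was also lost with slide series as a block (camera adjusted p = 0.0588), within the first series (0.0681), with median centring (0.0547), with dim probes filtered (0.0515) and without wild-type array 1 (0.0532), 2 (0.0525) or 3 (0.0527).

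On the mur arrays 3 lists passed downward. Of 35 measured genes of uptake hydrogenase, 11 fell and 2 rose (camera adjusted p = 0.0468, and adjusted p = 0.243 with an estimated correlation), with hupC (blr1722) at -1.04 and hypF (blr1735) at -0.70. The probe listed as hupA (bll6175) was among those that rose, at 1.40, but it is in this list by its symbol alone and may not belong to it. The call of this list was lost without mur array 2 (camera adjusted p = 0.0539) or 3 (0.101), with a normexp offset of 0 (0.0508) and with median centring (0.0505). The estimated correlation of this list was -0.006, also below the preset. Of 41 genes of nitrogen metabolism and denitrification, 8 fell and 2 rose (camera adjusted p = 0.0302, and adjusted p = 0.243 with an estimated correlation), a call lost without mur array 2 (camera adjusted p = 0.0539). Nitrate transport genes nrtC (blr2805) and nrtA (bll5734) had log2 ratios of -0.72 and -0.71, while the glutamine synthetase gene glnA (blr4949) rose, at 0.88. Of 9 genes of carbon dioxide fixation, 4 fell and 0 rose (camera adjusted p = 0.0321, and adjusted p = 0.496 with an estimated correlation). This call was lost without mur array 1 (camera adjusted p = 0.0642) or 2 (0.136). Of the 4 members that fell, cbbP (blr2582) and cbbX (blr2587) lost their calls without mur array 2 (limma adjusted p = 0.15 and 0.253). Without that array, cbbS (blr2586) kept a value on 1 mur array, at -0.53 against -1.03 in the main fit. The Rubisco gene cbbL (blr2585) had a log2 ratio of -0.75, and its call was lost with every spot kept (limma adjusted p = 0.0677), with a normexp offset of 0 (0.0554), within the first series or on the mur arrays alone (0.0703), with the deposited ratios (0.057), without mur array 1 (0.127) or 2 (0.206) and without wild-type array 1 (0.0548) or 3 (0.0565).

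Outside these lists, bll5338 was at least 8.82-fold higher in the mutant channel, bkdB (blr6333), of branched-chain keto acid breakdown, at least 3.26-fold and bll6847 at least 3.76-fold. The probe of bll5890 was at least 18.2-fold lower, with a log2 ratio of -4.41 ± 1.15 (SD, n = 3), and that of bll7206 at least 5.38-fold lower. The log2 ratio was -2.64 ± 1.56 for bsr3082, -2.04 ± 0.09 for bll0695, -1.98 ± 0.82 for bll5555 and -1.94 ± 0.96 for bsl5891 (SD, n = 3). The probes of bll7986, bll5191 and bsr4726 had log2 ratios of -1.82, -1.55 and -1.49, and blr7593 was at least 2.11-fold lower. Of 8465 probes tested, limma called 2224, of which 1116 were higher and 1108 lower. At a change of at least 2-fold, 172 were higher and 90 lower. The count was 757 without mur array 2, and 1353 within the first slide series, which holds all 3 mur arrays; with slide series as a block it was 2154.

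Across 8263 probes, the mean log2 ratios of the 2 groups of arrays correlated with Pearson r = 0.236 and Spearman rho = 0.322. This is across probes, which are not independent replicates. The value without any change depends on the doubted label. Unchanged groups in 20 simulations gave r = -0.498 and a covariance of -0.0119 where the shared RNA is the labelled Mn-deplete one, which enters the ratios with opposite signs. With the sign turned, chosen after the data were seen, they gave r = 0.504 and a covariance of 0.0121 where the Cy3 channels of both groups share an RNA. The observed covariance was 0.0466. These simulations assume that the 2 groups share RNA samples, which fixes r near the simulated values. Separate cultures for each group, or spread that arises on the arrays, would give other values without any change. The observed r is therefore not read against either simulated value. Within the first slide series, with 1 wild-type array, r was 0.15. Called in both groups, 258 probes were higher in both where independent lists would share 172.7, and 398 were lower in both where they would share 142.4. Probes higher on the wild-type and lower on the mur arrays numbered 91, against 171.4 for independent lists, and those lower on the wild-type and higher on the mur arrays 131, against 143.4. The values for independent lists leave out the shared RNA, and the simulated unchanged groups shared at most 0 calls, so the excess over either is not read as a shared effect.

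The third comparison, mur Mn-replete over wild type Mn-replete, is indirect and sums the ratios of the 2 groups of arrays. It rests on the label of the Cy3 channel of the mur arrays, which the levels above go against, so its directions and sizes hold only if that label is right. On this sum the mnoP probe (blr0095) was at least 746-fold higher and bll5338 at least 16.0-fold, while bll5890 was at least 29.9-fold lower. The irr probe (bll0768) had a log2 value of 3.81 (SE 0.19 from the fit over 6 arrays). The mntH probe (bll5044), with 1 wild-type array, had 8.62, and the mur probe (bll0797) 1.30 (SE 0.18). The sum also ranked high probes that stood out on the wild-type arrays alone, such as blr1115, at least 9.76-fold higher, and bll2512, with a log2 value of 3.28 (SE 0.29). A separate-channel fit of the mur Cy5 channel against the Mn-replete Cy3 channel, chosen after the data were seen, does not use the doubted channel as a condition. In it bll5890 was at least 36.3-fold lower (limma adjusted p = 0.0114). The mnoP probe, with a lower bound of 22.1-fold, did not pass (limma adjusted p = 0.114), and neither did blr1115 (0.816). The log2 values were 1.34 for irr (limma adjusted p = 0.299), 0.53 for mur (0.554), 2.69 for bll5338 (0.0477) and -0.32 for bll2512 (0.834). The mntH probe was not in this fit, which used probes measured on all 6 arrays. With every spot kept, its level was 12.2 ± 0.99 in the mur Cy5 channel. In the Mn-replete Cy3 channel of the wild-type arrays it was 8.44 ± 0.25 (SD, n = 3). The separate-channel fit called 33 of 8263 probes, 24 higher and 9 lower. On the sum, 4 lists passed upward and 2 downward, and each had an adjusted p = 0.391 with an estimated correlation. Ribosomal protein genes were higher for 39 of 53 (camera adjusted p = 4.51e-12, and adjusted p = 0.391 with an estimated correlation), and also passed upward on the separate-channel values (camera adjusted p = 3.96e-12). Genes of respiration and ATP synthase passed upward in both as well (camera adjusted p = 0.00132 on the sum, 0.00651 on separate channels, and adjusted p = 0.391 with an estimated correlation on the sum). The sum and the separate-channel fit both use the mur Cy5 and the Mn-replete Cy3 channels, so passing in both is not independent support. Their values correlated at r = 0.536. The other 4 lists that passed on the sum did not pass on the separate-channel values. Genes of chaperones and heat shock were higher on the sum for 22 of 41 (camera adjusted p = 0.00638, against 0.28 on separate channels, and adjusted p = 0.391 with an estimated correlation), with dnaK (blr0678) at 2.42 on the sum and 0.79 in the separate-channel fit (limma adjusted p = 0.464). Purine and pyrimidine biosynthesis passed upward on the sum (camera adjusted p = 0.00704, against 0.101 on separate channels, and adjusted p = 0.391 with an estimated correlation). Uptake hydrogenase passed downward on the sum (camera adjusted p = 0.00951, against 0.28 on separate channels, and adjusted p = 0.391 with an estimated correlation). Flp pilus passed downward on the sum (camera adjusted p = 0.00638, and 0.053 with median centring, and adjusted p = 0.391 with an estimated correlation), but its direction turned upward on the separate-channel values, where it did not pass (camera adjusted p = 0.956). There ctpC (bll1440) had 0.070, ctpD (bll1439) 0.27, ctpE (bll1438) 0.85 and ctpG (bll1436) 0.24, with 0 of the 16 measured members called. On the separate-channel values 3 lists passed that did not pass on the sum, tested with the preset correlation only. The correlation estimated on the ratios was 0.201 for motility, 0.517 for carbon dioxide fixation and -0.049 for the TCA cycle. For ribosomal proteins it was 0.365. Where it lies above the preset of 0.01, the preset may give too small a p-value. Motility and chemotaxis genes passed upward (camera adjusted p = 4.62e-17), with a median log2 value of 0.49, 54 of 65 above 0 and 7 called higher. On the sum their direction was downward (median -0.020, camera adjusted p = 0.877). Genes of carbon dioxide fixation passed downward (camera adjusted p = 0.00137, against 0.435 on the sum), with a median of -1.13, 7 of 7 below 0 and 0 called. Genes of the TCA cycle and pyruvate passed upward (camera adjusted p = 0.0441, against 0.435 on the sum), with a median of 0.28 and 1 of 19 called. Of 8453 probes, limma called 3262, with 1714 higher and 1548 lower. The count was 793 with slide series as a block, 174 within the first series, both resting on 1 wild-type array, and 2151 without wild-type array 2.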

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

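The rule for the control probes and the test of a dye effect were chosen only after the result was seen. The bounds of the slope test were written before any slope was computed, but after the ratios and channel levels that prompted it had been seen.

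Signals stood out in control spots that no comparison uses, at 2 control probes named in the files only by sequence identifiers. The stronger had a mean log2 ratio of 4.79 ± 1.08 on the mur arrays and -0.23 ± 0.15 on the wild-type arrays (SD, n = 3). Its lowest level in the mutant channel, 9.76 on the log2 scale, was above its highest level in any wild-type channel, 6.68. The weaker had a mean log2 ratio of 1.38 ± 0.41 on the mur arrays and -0.24 ± 0.05 on the wild-type arrays (SD, n = 3), with a lowest mutant level of 7.69 above its highest wild-type level of 6.70. Empty spots reached 6.47 in a wild-type channel, so the wild-type levels of both control probes were close to background and their ratios are not exact. What the 2 control probes detect is not given in the sources used here. Among the other control probes, Stratagene oligo 3 lay furthest from 0 and was low in both groups. Its mean log2 ratio was -2.04 ± 0.36 on the wild-type and -1.87 ± 0.28 on the mur arrays (SD, n = 3). A dye effect could give such a repeated ratio, which was not tested.

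The Cy3 channel of the mur arrays, labelled wild type Mn-deplete, did not carry the response to manganese withdrawal seen on the wild-type arrays. Over 2346 probes called on the wild-type arrays, the slope of its level, less the Mn-replete level, on that response was -0.062 ± 0.18 (SD over 9 array pairs), where Mn-deplete RNA would give about 1. The ratio of each wild-type array on that of the others gave 0.972 ± 0.255. This argues against the label as written, and also against a dye effect on each probe as the whole cause, because the mur ratios had a slope of 0.163 ± 0.094 on the wild-type ratios. A candidate explanation is that the channel holds wild-type Mn-replete RNA; a culture meant to be deplete that did not respond would give the same slope, was not tested and stays open.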

How the results depend on the processing

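The separate-channel fit, the list tests by slide series or without single arrays or on separate channels, the correlation of the groups within the first series, the simulation in which the Cy3 channels share an RNA and the 32 sign patterns were chosen after the data were seen; the others were planned. Array signal over background limits dim probes. The 3 call counts moved as follows, and the cause was not tested except that fewer arrays enter some fits. With slide series as a block, the wild-type comparison called 228 probes and the indirect one 793. Within the first series they called 59 and 174, and the mur arrays 1353, as in a fit of these arrays alone (1353). At 2-fold the counts were 368, 262 and 1173. Without single arrays they ranged from 900 to 2562 (wild type), 757 to 2206 (mur arrays) and 2151 to 3068 (indirect). The separate-channel fit called 33. Same-numbered arrays deviated with r of 0.295, 0.225 and 0.034. Arrays with different numbers gave -0.259 to 0.115, the highest for array 3 of the wild type with mur array 2. Whether the numbers pair the arrays is therefore not settled. The replicate block gave 1691, 1412 and 2574 calls. It gives the 2 groups opposite signs, for the RNA that the doubted label says they share. The deviations of same-numbered arrays were positive, so this block does not capture them and its counts do not test the pairing. The indirect separate-channel log2 values had the opposite sign for bll2512 (-0.32), hspH (bll0729, -0.36), ctpC (bll1440, 0.070), ctpD (bll1439, 0.27), ctpE (bll1438, 0.85) and ctpG (bll1436, 0.24). With median centring 7 lists passed on the wild-type arrays in place of 2. With an estimated correlation 0 passed in any comparison, against 2, 9 and 6. Without single arrays 2 to 3, 7 to 10 and 6 passed, and 5 on separate channels for the indirect comparison, 2 of them shared with the sum; the other 3 were motility, which turned from down to up, carbon dioxide fixation and the TCA cycle. The correlation between the groups stayed between 0.168 and 0.275 without single arrays. Values of named genes lost their call with the same sign 17, 33 and 64 times in the 3 comparisons, and kept their side of the threshold 661, 1167 and 935 times. The losses include genes that passed the adjusted p but fell short of the 2-fold setting. The planned spot median was not run because the files used here hold spot means. Each group of 3 arrays allows 4 sign patterns, too few for a share under 0.05: the real pattern, the 1 with as many calls, gave 2394 on the wild-type and 2224 on the mur arrays, and the highest other gave 0. For the sum, with each of the 6 arrays signed on its own, 1 of 32 patterns, the real one, gave as many as 3262 calls. The highest other, with all mur arrays turned, gave 1434. Arrays of a group correlate with each other, so turning 1 of them lowers the count whatever the source of the calls. A dye effect that is the same on every array would also favour the real pattern, so no source is excluded. The patterns say nothing about the doubted label. Turning same-numbered arrays together, whose pairing is not settled, gave 0 calls at most in the other 3 of 4 patterns.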

Other observations

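The test of gene order was chosen after neighbouring loci had been seen among the named genes, and the runs described here were chosen after their values were seen.

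Several runs of neighbouring loci on 1 strand changed together by at least 2-fold. On the wild-type arrays, the 3 loci from bll0178 to bll0180, listed as cobT, bll0179 and cobS, had log2 ratios of 1.05 to 1.58, and the 3 loci from bll5042 to bll5044 (mntH) had 1.25 to 4.74. The 5 loci from bll5842 to bll5846 had -2.19 to -1.03. On the mur arrays, against the channel labelled wild type Mn-deplete, the 11 loci from bll6847 to bll6857 had 1.05 to 3.05, the 4 loci from bll1185 (atpB) to bll1188 (atpA) 1.28 to 1.73, and the 3 bkd loci from blr6331 to blr6333 1.25 to 2.20. The 5 loci from bll7203 to bll7207 were higher on the wild-type arrays, at 1.35 to 1.83, and 3 of them, bll7205 to bll7207, were lower on the mur arrays, at -2.76 to -1.41.

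On the wild-type arrays, 465 of 5491 neighbouring same-strand pairs were called in the same direction, against a mean of 222.4 and a highest value of 268 in 1000 shuffles, which argues against calls independent of gene order. Shared transcription of neighbouring genes may contribute, as a hypothesis that was not tested directly. None of the pairs, 0%, lay in the same printing block, which argues against closeness within a block. A slide layout that follows locus numbers in another way stays open. Neighbours on opposite strands were called in the same direction in 158 of 2667 pairs, or 5.92%, against 8.47% on the same strand. The ratio of these shares was 0.7 (bootstrap SD 0.062), between the bounds set beforehand. The opposite-strand share was also above that of the highest same-strand shuffle, 268 of 5491 pairs, so the excess is not limited to neighbours on 1 strand.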
